A study of Mus musculus with 18 samples.

How the data were processed

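The labels describe 18 libraries of total RNA from neutrophils of adult C57BL/6 mice, 3 each from BM, Blood, Spleen, Lung, Intestine and Skin, sorted at purities typically over 95%. RNA was amplified with the Ovation Single Cell kit and read as 61-nt single ends on a Genome Analyzer IIx, per the labels' protocols. CASAVA, RSEM 1.3.1 and limma were used on mm10 (GRCm38), per the submitters' processing notes, which give neither their order nor the annotation. The deposited table holds a signal value for each of 32328 genes in each library, on a linear scale. Although its name says TPM, the deposited values carry no gene length: each is an estimated count plus 0.5, divided by an effective library size plus 1 and multiplied by 1e6, as read from the values. The design, fixed before the data were examined, assumed TPM, and the same limma test on log2(value + 1) was kept for these scaled estimated counts. Levels of different genes in a library are therefore not comparable by transcript number.

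Estimated counts were recovered from the floor of each library and totalled 2.94e+06 (Lung replicate 1) to 1.21e+07 (Spleen replicate 2), and the effective libraries from 2.31 to 13.8 times 1e6. Gene symbols, types and positions came from GENCODE vM21, which named 31820 of the identifiers and left 508 unnamed. Genes with a value of at least 1 in at least 3 libraries were tested, 16157 in all. A linear model with 6 group means was fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8, jsonlite 2.0.0), leaving 12 residual degrees of freedom, with moderated tests, a trended prior and Benjamini-Hochberg adjustment over all tested genes at 0.05. All adjusted p-values of single genes are from this limma fit. The contrasts were each tissue minus Blood, and each tissue minus the mean of the other 5, beside an F test of any difference. Log2 differences on log2(value + 1) understate changes of low genes. Where all libraries of the lower group had 0 counts, a lower bound on the fold was computed from a floor of 3 counts per library, which covers counting error only. The median log2 difference over all genes shifted by up to 0.30 (Skin against the others, quantile) and -0.33 (Intestine against the others, quantile) under other scalings.

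Gene lists, 20 lists of states and 15 of other-cell markers, were written before the data were examined and tested with camera at a preset correlation of 0.01, adjusted within each comparison. Each was tested again with the correlation estimated per list, and members were also adjusted over the list alone. The genes named were set by rule before the data were examined. Against Blood these were the 8 higher and 8 lower protein-coding genes with the largest log2 difference among those that passed, with a mean of at least 20 in the higher group and the 3 libraries of one tissue all above the 3 of the other, leaving out markers of other cells. Against the other tissues they were 8 higher and 4 lower. From each list described, up to 4 members with the smallest adjusted p were named, and others were fixed in advance, among them Ly6g, Cxcr2, Cxcr4, Mpo, Elane, Ltf, Camp, Mki67, Vegfa, Il1b, S100a8 and S100a9. Some genes set by these rules are not reported here. Which lists are described was chosen after the results were seen. Transcripts with 20-mers shared with Gm10800 at 20% or more formed a group of 12 genes. Near-identical copies share reads, so values of Hbb-bs and Hbb-bt, Hba-a1 and Hba-a2, Bcl2a1b and Bcl2a1d, Hspa1a and Hspa1b, and of the Gbp, Ifitm and Gimap families are uncertain for the single gene. Genes that overlap on opposite strands are uncertain too, since strand use is not stated.

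The fit was tested on counts simulated from the real means and library sizes with 200 genes changed. All genes of a simulated library were given the same spread. Of the genes changed 8-fold, 6.06% were recovered in BM against Blood, 19.7% in Spleen, 30.3% in Lung, 0% in Intestine and 56.1% in Skin, and without the Skin libraries 98.5%, 97.0%, 95.5% and 95.5% of the first 4. Against the other tissues 65.2% in BM, 78.8% in Blood, 81.8% in Spleen, 72.7% in Lung, 75.8% in Intestine and 84.8% in Skin were recovered. No gene was called in the wrong direction. The fixed design gives 1 spread per gene to all libraries, and the Skin libraries spread more than the others, so genes that did not pass outside Skin may still differ. A first version of this test required over 50% recovery against Blood and failed. That requirement was replaced by limits on wrong directions and on unchanged genes called outside Skin, and the design was kept. Of 15960 genes in Skin, 252 unchanged ones were called against Blood and 1847 against the others, with at most 1 elsewhere. Weights per library estimated by limma were 0.107 to 0.440 in Skin. A list raised 2-fold was called in each of the 11 comparisons. Of lists not raised 2 were called (1 each in BM and Blood against the others), 0 with an estimated correlation. As 152 of 192 real list calls were lost that way, this does not test the preset correlation. Alternatives changed the pseudocount (0.1 and 5), the filter (none, or at least 5), the scaling, a block by replicate number or by letter, the prior, weights and the libraries used. Of the 406 calls of genes set by the naming rules or given in the text, 256 held in every alternative run for them.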

Results

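Neutrophils, the granule-carrying phagocytes that are made in bone marrow and circulate briefly in blood, were compared between 6 tissues of C57BL/6 mice aged 8 to 12 weeks. Cells were sorted with antibodies against CD45, CD11b and Ly6G, and 3 libraries each came from bone marrow (BM), Blood, Spleen, Lung, Intestine (colon) and Skin (ear), 18 in all. The series asks how neutrophils differ from tissue to tissue. The deposited values are estimated read counts per gene, scaled by an effective library size and not divided by gene length. They are called scaled counts here. Estimated counts totalled 8.54e+06, 9.19e+06 and 9.99e+06 in BM, 8.19e+06, 9.07e+06 and 9.38e+06 in Blood, 1.00e+07, 1.21e+07 and 8.72e+06 in Spleen, 2.94e+06, 1.08e+07 and 9.38e+06 in Lung, 9.86e+06, 9.92e+06 and 1.09e+07 in Intestine and 1.04e+07, 5.68e+06 and 5.96e+06 in Skin. Between 9179 (Skin replicate 2) and 16189 genes (Spleen replicate 2) were above the floor of a library. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries.

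Skin and Intestine libraries differed from the rest in what their reads came from. Transcripts related to Gm10800, a predicted gene, took 54.7, 43.6 and 26.4% of the estimated counts in the Skin libraries and 1.07 to 9.02% elsewhere. Mitochondrially encoded genes took 23.2, 8.58 and 8.24% in Intestine and at most 2.87% in the other libraries. The residual spread per library was 1.28 to 1.57 on the log2 scale in Skin and 0.534 to 0.952 in the other 15 libraries.

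**Figure D1:**
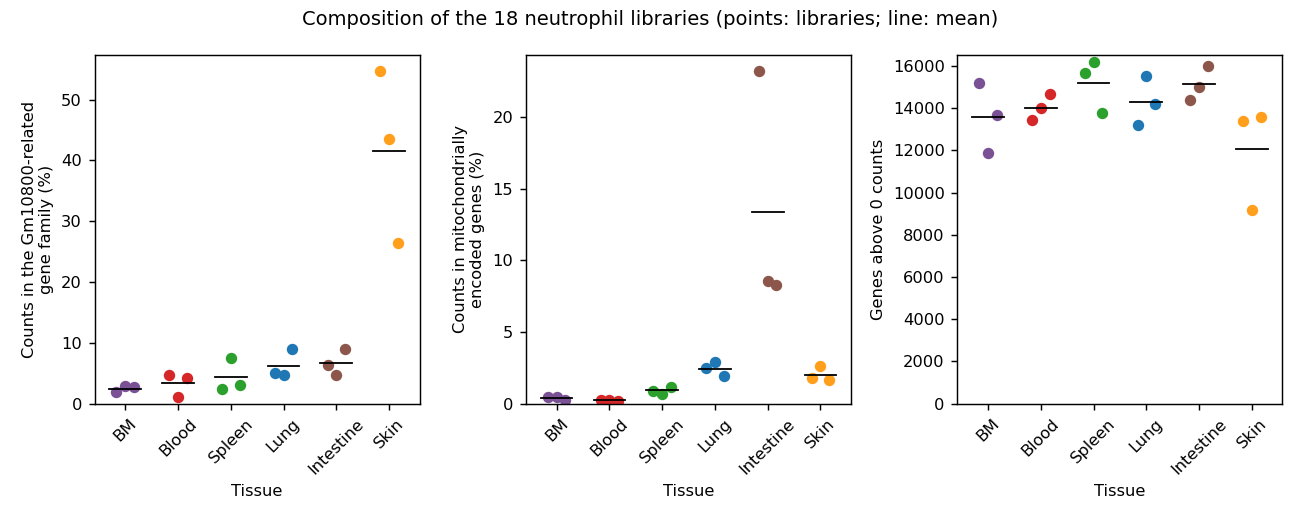
Share of counts from Gm10800-related genes (percent), share from mitochondrially encoded genes (percent) and genes above 0 counts in each of the 18 libraries (points) with the mean of each tissue (line). The 3 Skin libraries have the highest Gm10800-related shares (54.7, 43.6 and 26.4%) and the 3 Intestine libraries the highest mitochondrial shares (23.2, 8.58 and 8.24%).

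The genes that separated the tissues included those that mark stages of neutrophil life. Camp, the cathelicidin antimicrobial peptide of specific granules, averaged 2806 ± 292 scaled counts in BM (SD, n = 3, as for all group means given here), 134 ± 104 in Blood and 0.992 ± 1.18 in Lung. Ltf, the iron-binding granule protein lactoferrin, ran from 7949 ± 218 in BM to 17.9 ± 29.7 in Skin, and Mpo, myeloperoxidase of azurophil granules, from 35.6 ± 13.7 in BM to 0.445 ± 0.524 in Intestine. S100a9, a calcium-binding alarmin abundant in neutrophils, was 19602 ± 3084 in BM, 14190.4 ± 909 in Blood, 4798 ± 1169 in Spleen, 4433 ± 2695 in Lung, 4193 ± 3752 in Skin and 358 ± 83.1 in Intestine. Its partner S100a8 was 4575 ± 1510.0 in BM and 91.9 ± 17.8 in Intestine. The chemokine receptor Cxcr2 was 3619 ± 191 in Blood and 77.5 ± 19.2 in Intestine. Il1b, which encodes the inflammatory cytokine interleukin-1 beta, was 667 ± 74.5 in Intestine, 914 ± 188 in BM, 2494 ± 716 in Spleen, 3193 ± 552 in Blood, 9965 ± 5031 in Lung and 10203 ± 10319.5 in Skin. The gene of the sorting marker itself, Ly6g, was 403 ± 144 in BM, 136 ± 89.0 in Blood, 14.3 ± 8.11 in Spleen, 25.8 ± 9.94 in Lung, 9.11 ± 15.4 in Skin and 1.298 ± 1.59 in Intestine.

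By limma's F test with Benjamini-Hochberg adjustment, 5159 of the 16157 tested genes differed between tissues. They included Camp (adjusted p = 6.65e-07), Ltf (4.27e-06), S100a9 (4.56e-06), Ly6g (1.85e-05), Mpo (8.82e-05), Cxcr2 (0.000153), S100a8 (0.000154), Il1b (0.000406), Cxcr4 (0.0230) and Mki67 (0.0294). Vegfa did not pass (adjusted p = 0.196 by limma), and Elane, 4.09 ± 4.98 in BM, was below the filter. The first principal component held 30.1% of the variance and the second 18.2%. Blood libraries differed from each other by a root mean square of 1.04 log2 units, the lowest of the 6 tissues, and Skin libraries by 2.55, the highest. Among the 35 lists of genes fixed before the data were examined, camera called 192 of 385 tests over the 11 comparisons, and 40 of these held with an estimated correlation. The 40 were 3 of BM, 10 of Spleen, 4 of Lung, 0 of Intestine and 3 of Skin against Blood, and 3 of BM, 2 of Blood, 4 of Spleen, 6 of Lung, 0 of Intestine and 5 of Skin against the other tissues.

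**Figure D2:**
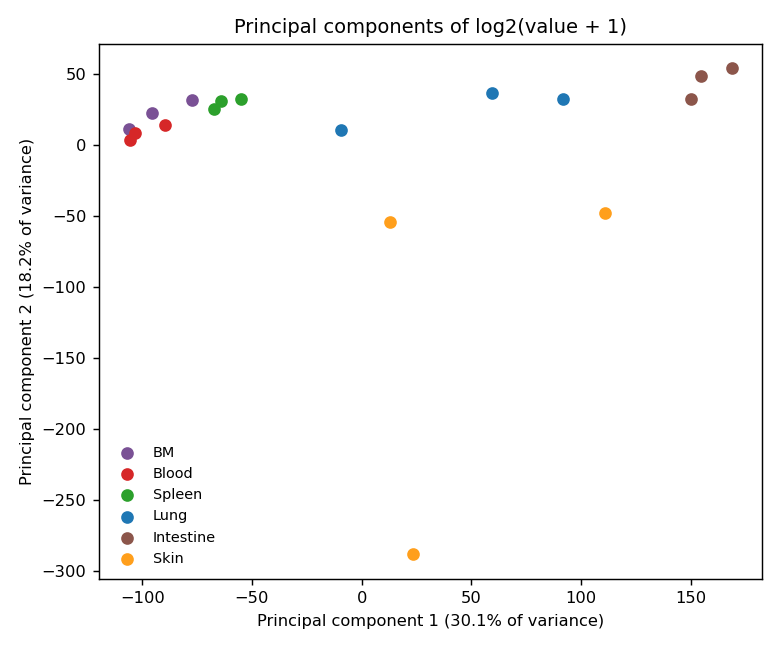
First against second principal component of the log2 values of the tested genes (percent of variance on each axis), 1 point per library, coloured by tissue. The 3 Intestine libraries lie at 150.3 to 169 on the first component, and Skin replicate 2 lies at -289 on the second.

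BM against Blood compares neutrophils before and after release into the circulation. Single genes of granules and of cell division were higher in BM, while most members of those lists did not pass and the granule lists were lost with an estimated correlation. Camp stood at 2806 ± 292 scaled counts in BM and 134 ± 104 in Blood (log2 difference 4.65 ± 0.95 SE, limma adjusted p = 0.0447, lost in 12 of 21 alternatives), and Mpo at 35.6 ± 13.7 and 1.31 ± 1.08 (4.03 ± 0.67, adjusted p = 0.00597, lost in 3 of 21). Top2a, the topoisomerase of dividing cells, was higher by 5.58 ± 0.94 and Rrm2, a subunit of ribonucleotide reductase, by 4.75 ± 0.99, a call lost in 10 of 21 alternatives. Fcnb, the secreted lectin ficolin B, was also higher (4.32 ± 0.62), as was 4930438A08Rik (4.38). Lower in BM were Apol11b, of the apolipoprotein L family (-5.78 ± 0.79), Fosb, a subunit of the AP-1 transcription factor (-4.17 ± 0.55, adjusted p = 0.00108 by limma), Plk2, a polo-like kinase (-4.75), Socs3, an inhibitor of cytokine signalling (-3.21), and the interferon-induced Gbp2 (-3.89), Gbp5 (-4.41, lost in 6 of 21) and Ifitm1 (-3.23, lost in 7 of 21). The Y-linked Eif2s3y (6.09) and Ddx3y (4.44) were higher in BM, with a mean of 0.348 and 4.91 in Blood, and the labels do not give the sex of the mice. On mm10 (GRCm38), Camp (ENSMUSG00000038357) lies on chromosome 9, 109847379 to 109849617, Fosb (ENSMUSG00000003545) on chromosome 7, 19302696 to 19310051 and Mpo (ENSMUSG00000009350) on chromosome 11, 87793581 to 87804413.

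Specific and gelatinase granule genes had 1 higher, 0 lower and 21 not passing among 22 tested, and 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.66e-10, 0.115 with an estimated correlation). Camp (4.65) passed, while Cybb (3.21) and Ltf (4.26) did not. Among 10 tested azurophil granule genes, 1 higher and 0 lower passed, 9 did not, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0101, 0.185 with an estimated correlation). Mpo (4.03) passed, while Serpinb1a (3.17) and Lyz2 (1.61) did not. Of 30 tested cell cycle genes, 2 were higher, 0 lower and 28 did not pass, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.14e-15, 0.0255 with an estimated correlation). Top2a (5.58) and Rrm2 (4.75) passed, while Ccnb1 (3.37) and Kif11 (3.46) did not. Interferon-gamma response genes had 0 higher, 2 lower and 25 not passing among 27 tested, and 0 higher and 8 lower adjusted over the list alone (camera adjusted p = 5.94e-12, 0.00258 with an estimated correlation). Gbp2 (-3.89) and Gbp5 (-4.41) passed, while Gbp3 (-3.89) and Irgm1 (-2.49) did not. Among 35 tested immediate early and heat shock genes, 0 higher and 1 lower passed, 34 did not, with 0 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.000381, 0.136 with an estimated correlation). Fosb (-4.17) passed, while Atf3 (-1.93) and Maff (-2.41) did not. Of 30 tested type I interferon response genes, 0 were higher, 0 lower and 30 did not pass, with 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 3.91e-10, 0.213 with an estimated correlation). The smallest adjusted p-values belonged to Rtp4 (-3.73), Zbp1 (-3.58) and Oasl1 (-2.93), which did not pass.

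Erythroid markers had 0 higher, 3 lower and 7 not passing among 10 tested, and 0 higher and 7 lower adjusted over the list alone (camera adjusted p = 9.13e-11, 0.00740 with an estimated correlation). Hbb-bt (-6.83), Hbb-bs (-5.94) and Alas2 (-5.27, lost in 12 of 21 alternatives) passed, while Hba-a2 (-4.86) did not. Among 14 tested B-cell markers, 0 higher and 0 lower passed, 14 did not, with 10 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.02e-09, 0.0512 with an estimated correlation). Pax5 (3.26) and Ms4a1 (2.97) did not pass. In all, 33 of the 16157 genes passed, 17 higher and 16 lower (more were lower in 11 of 21 alternatives). In 19.3% of the tested genes the 3 libraries of one tissue all lay above the 3 of the other, against 10% by chance. The count was 339 without the Skin libraries, 578 with a weight per library and 463 with only the 6 libraries compared. It was 19 without BM replicate 2, and 17 and 11 without Blood replicate 1 and 2.

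Spleen against Blood was marked by genes of lymphocytes and antigen presentation. H2-Aa, a chain of the class II antigen-presenting molecule, stood at 238 ± 79.7 scaled counts in Spleen and 6.17 ± 8.78 in Blood (log2 difference 5.78 ± 0.79 SE, limma adjusted p = 0.000601). Ikzf3, the lymphoid transcription factor Aiolos, was 159 ± 47.5 and 1.93 ± 2.54 (6.08 ± 0.83, adjusted p = 0.000601 by limma). Btla, an inhibitory receptor of lymphocytes (5.69 ± 1.10), Snn (5.84) and the lymphocyte GTPases Gimap1 (5.67) and Gimap4 (5.64, lost in 10 of 22 alternatives) were higher too. Itpr3, a calcium channel of the endoplasmic reticulum, was 0 in Blood and at least 144-fold higher in Spleen, and Eif2s3y was higher by 6.42. Lower in Spleen were Prok2, a secreted factor acting on blood vessels (-4.94 ± 1.04, lost in 9 of 22), Lcn2, the iron-sequestering lipocalin 2 (-2.49 ± 0.57, lost in 11 of 22), Acod1, the enzyme that makes itaconate (-3.17, lost in 14 of 22), and Gpr27 (-3.93, lost in 8 of 22). Apol11b (-5.62, 0.17 with BM as the reference), Gbp2 (-3.13, 0.76 with BM as the reference) and Ifitm3 (-2.69) were lower as well. On mm10, H2-Aa (ENSMUSG00000036594) lies on chromosome 17, 34282744 to 34287823 and Ikzf3 (ENSMUSG00000018168) on chromosome 11, 98464902 to 98546031. The fixed neutrophil genes reported did not pass here, with log2 differences of -3.11 for Ly6g, -1.59 for S100a9 and -0.39 for Il1b.

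Of 14 tested class II antigen presentation genes, 4 were higher, 0 lower and 10 did not pass, with 9 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.14e-15, 0.00534 with an estimated correlation). Examples were H2-Ab1 (5.40), Cd74 (4.89), H2-Aa (5.78) and H2-Eb1 (4.55). B-cell markers had 11 higher, 0 lower and 3 not passing among 14 tested, and 13 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.21e-38, 0.000527 with an estimated correlation). Pax5 (7.53), Ighm (5.25) and Blk (at least 128-fold higher) were among them. Among 15 tested T and NK cell markers, 1 higher and 0 lower passed, 14 did not, with 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.39e-08, 0.0239 with an estimated correlation). Cd2 (4.55, lost in 6 of 22 alternatives) passed, while Trbc2 (mean 4.40 against 0) and Gzma (mean 6.24 against 0) did not. Of 22 tested specific and gelatinase granule genes, 0 were higher, 1 lower and 21 did not pass, with 0 higher and 2 lower adjusted over the list alone (camera adjusted p = 2.53e-11, 0.0512 with an estimated correlation). Lcn2 (-2.49) passed, while Ngp (-3.43) and Itgb2l (-2.39) did not. Neutrophil identity genes had 0 higher, 0 lower and 24 not passing among 24 tested, and 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.39e-08, 0.221 with an estimated correlation). The smallest adjusted p-values belonged to Ly6g (-3.11), S100a9 (-1.59) and Wfdc21 (-2.10), which did not pass. Among 30 tested cell cycle genes, 0 higher and 0 lower passed, 30 did not, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 7.89e-10, 0.0468 with an estimated correlation). The smallest adjusted p-values belonged to Mcm3 (3.60), Top2a (3.36) and Rrm1 (3.25), which did not pass.

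Of 27 tested interferon-gamma response genes, 0 were higher, 1 lower and 26 did not pass, with 1 higher and 4 lower adjusted over the list alone (camera adjusted p = 2.25e-05, 0.0239 with an estimated correlation). Gbp2 (-3.13, 0.76 with BM as the reference) passed, while Irgm1 (-2.19) and Ciita (3.47) did not. Erythroid markers had 0 higher, 5 lower and 5 not passing among 10 tested, and 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 2.14e-15, 0.00147 with an estimated correlation). Hbb-bs (-7.54), Hbb-bt (-7.56), Hba-a2 (-5.86) and Alas2 (-5.46, lost in 10 of 22 alternatives) were among them. Among 28 tested angiogenic factors, 0 higher and 1 lower passed, 27 did not, with 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00510, 0.0239 with an estimated correlation). Prok2 (-4.94) passed, while Hif1a (-1.31) and Anxa1 (-1.22) did not. In all, 98 of the 16157 genes passed, 77 higher and 21 lower (22 and 26 with BM as the reference). In 29.2% of the tested genes the 3 libraries of one tissue all lay above the 3 of the other. Chance is not 10%, Spleen floors being lower. The count was 400 without the Skin libraries, 1725 with a weight per library and 1155 with only the 6 libraries compared. It was 31, 24 and 53 without Blood replicate 1, 2 and 3. It was 23, 65 and 29 without Spleen replicate 1, 2 and 3, and 48 with BM as the reference.

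Lung against Blood showed genes of blood vessels, inflammatory signalling and early response higher. Of the specific and gelatinase granule genes 6 of 22 were lower, a list call lost with an estimated correlation. Adgrf5, an adhesion receptor of lung endothelium and epithelium, stood at 1096 ± 584 scaled counts in Lung and 3.69 ± 4.82 in Blood (log2 difference 8.20 ± 0.81 SE, limma adjusted p = 6.63e-06). Cav1, the coat protein of caveolae, was 525 ± 301 and 3.36 ± 3.95 (7.13 ± 0.91). Clec14a, an endothelial lectin, was 0 in Blood and at least 606-fold, and 388-fold without Lung replicate 1, higher in Lung. Jcad, a protein of endothelial junctions (7.45), the cytochrome Cyp4b1 (7.16), Emp2 (7.16), the guidance factor Sema3c (7.08) and complement C7 (6.86) were also higher. The granule genes Camp (-5.96 ± 0.95, adjusted p = 0.000520 by limma), Ngp (-5.24 ± 1.02) and Ltf (-4.47 ± 1.06) were lower in Lung, with Camp at 0.992 ± 1.18 against 134 ± 104. Prok2 (-4.83), the cadherin Cdh23 (-4.70), Kirrel3 (-5.10), Zfp947 (-5.71) and Cyren (-4.74) were lower too, and Apol11b, 0 in Lung, was at least 142-fold lower. Il1b averaged 9965 ± 5031 in Lung and 3193 ± 552 in Blood and did not pass (1.53 ± 0.63, adjusted p = 0.181 by limma). Vegfa, the vascular growth factor, was 167 ± 20.2 and 58.4 ± 11.7 and did not pass (1.51 ± 0.62). On mm10, Adgrf5 (ENSMUSG00000056492) lies on chromosome 17, 43360451 to 43459557 and Ngp (ENSMUSG00000032484) on chromosome 9, 110419747 to 110423012.

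Of 33 tested NF-kappaB response and cytokine genes, 14 were higher, 0 lower and 19 did not pass, with 18 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.53e-10, 0.00262 with an estimated correlation). Tnfaip3 (5.17), Nfkbia (3.05), Il1a (5.60) and Ccrl2 (5.68) were among them. Immediate early and heat shock genes had 14 higher, 0 lower and 21 not passing among 35 tested, and 18 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.98e-11, 0.0107 with an estimated correlation). Examples were Nr4a1 (5.38), Fosb (4.02), Nr4a3 (5.94) and Atf3 (3.75). Among 28 tested angiogenic factors, 5 higher and 2 lower passed, 21 did not, with 8 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0375, 0.0952 with an estimated correlation). Thbs1 (4.14), Pdgfb (4.23), Nrp1 (4.37) and Prok2 (-4.83) were among them. Of 22 tested specific and gelatinase granule genes, 0 were higher, 6 lower and 16 did not pass, with 0 higher and 8 lower adjusted over the list alone (camera adjusted p = 1.64e-07, 0.131 with an estimated correlation). Examples were Camp (-5.96), Ngp (-5.24), Ltf (-4.47) and Lcn2 (-2.40). Type I interferon response genes had 0 higher, 1 lower and 29 not passing among 30 tested, and 0 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.03e-06, 0.271 with an estimated correlation). Oas3 (-2.39) and Isg20 (-2.16) did not pass. Among 14 tested class II antigen presentation genes, 4 higher and 0 lower passed, 10 did not, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.97e-06, 0.0847 with an estimated correlation). Examples were H2-Ab1 (4.86), Cd74 (4.37), H2-Aa (5.25) and H2-Eb1 (3.92).

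Markers of other cell types differed in the same Lung libraries. Of 14 tested endothelial markers, 13 were higher, 0 lower and 1 did not pass, with 14 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.47e-20, 0.0107 with an estimated correlation). Cdh5 (8.31), Eng (6.11), Tek (6.90) and Calcrl (4.05) were among them. Lung epithelial markers had 7 higher, 0 lower and 4 not passing among 11 tested, and 9 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.13e-07, 0.115 with an estimated correlation). Examples were Cldn18 (5.25), Slc34a2 (5.70), Lamp3 (4.18) and Ager (4.88). Among 12 tested fibroblast markers, 8 higher and 0 lower passed, 4 did not, with 10 higher and 0 lower adjusted over the list alone (camera adjusted p = 5.10e-11, 0.0847 with an estimated correlation). Sparc (5.69), Pdgfra (4.24), Col1a1 (3.75) and Mgp (3.77) were among them. Of 10 tested alveolar macrophage markers, 4 were higher, 0 lower and 6 did not pass, with 6 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.03e-06, 0.0624 with an estimated correlation). Examples were Mrc1 (5.40), Car4 (at least 170.1-fold higher), Ear2 (4.06, -0.28 with BM as the reference) and Ear1 (at least 62.6-fold higher). Erythroid markers had 0 higher, 6 lower and 4 not passing among 10 tested, and 0 higher and 7 lower adjusted over the list alone (camera adjusted p = 5.33e-07, 0.0247 with an estimated correlation). Hbb-bt (-5.75, 1.08 with BM as the reference), Slc4a1 (at least 26.8-fold lower), Hbb-bs (-4.11, 1.83 with BM as the reference) and Alas2 (-4.30, lost in 8 of 22 alternatives, 0.97 with BM as the reference) were among them. In all, 1017 of the 16157 genes passed, 852 higher and 165 lower (889 and 365 with quantile normalization). In 32.1% of the tested genes the 3 libraries of one tissue all lay above the 3 of the other, against 10% by chance. The count was 2533 without the Skin libraries, 4626 with a weight per library and 2377 with only the 6 libraries compared. It was 571 and 552 without Blood replicate 1 and 2, and 463 and 571 without Lung replicate 1 and 2.

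Intestine against Blood was the comparison with the most genes, with markers of fibroblasts, plasma cells and intestinal epithelium higher and neutrophil identity genes lower. Of the 18 lists called, 0 held with an estimated correlation. Col6a3, a chain of type VI collagen, stood at 1047 ± 247 scaled counts in Intestine and 2.15 ± 0.648 in Blood (log2 difference 8.37 ± 0.95 SE, limma adjusted p = 3.98e-06). Adamdec1, a metalloprotease-like protein of the gut mucosa, was 1764 ± 841 and 5.76 ± 5.35 (8.19 ± 0.80). Smooth muscle myosin Myh11 (7.78 ± 0.80), the matrix proteins Col12a1 (8.16), Dpt (7.96), Nid1 (7.92) and Tnc (7.92) and the binding protein Igfbp7 (7.78) were higher. Ly6g averaged 1.298 ± 1.59 against 136 ± 89.0 (-5.92 ± 0.95, adjusted p = 0.000103 by limma) and S100a9 was 358 ± 83.1 against 14190.4 ± 909 (-5.33 ± 0.58). S100a8 (-5.25), Cxcr2 (-5.56), Ltf (-3.83), Camp (-3.66), Il1b (-2.25) and Cxcr4 (-2.20) were lower as well. Among the other lower genes were Stfa2l1, a cysteine protease inhibitor (-6.52 ± 0.90), the interferon-induced Rtp4 (-6.27) and Slfn4 (-6.18), Sirpb1a (-5.94), Ifitm6 (-5.93) and Kif23 (-5.92). Cdh23, 0 in Intestine, was at least 252-fold lower. On mm10, Col6a3 (ENSMUSG00000048126) lies on chromosome 1, 90765923 to 90843971 and Ly6g (ENSMUSG00000022582) on chromosome 15, 75155240 to 75159126.

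Among 24 tested neutrophil identity genes, 0 higher and 22 lower passed, 2 did not, with 0 higher and 22 lower adjusted over the list alone (camera adjusted p = 3.48e-17, 0.0844 with an estimated correlation). Examples were S100a9 (-5.33), Itgb2 (-3.49) and Mxd1 (-3.97). Of 22 tested specific and gelatinase granule genes, 0 were higher, 17 lower and 5 did not pass, with 0 higher and 19 lower adjusted over the list alone (camera adjusted p = 4.67e-11, 0.0844 with an estimated correlation). Lcn2 (-4.92), Hp (-5.001), Slpi (-4.34) and Adam8 (-3.08) were among them. Pattern recognition genes had 2 higher, 14 lower and 12 not passing among 28 tested, and 3 higher and 14 lower adjusted over the list alone (camera adjusted p = 0.000131, 0.0863 with an estimated correlation). Examples were Clec7a (-3.76), Myd88 (-3.72), Clec4e (-3.36) and Fcer1g (-3.84). Among 30 tested type I interferon response genes, 1 higher and 14 lower passed, 15 did not, with 1 higher and 20 lower adjusted over the list alone (camera adjusted p = 7.15e-07, 0.244 with an estimated correlation). Oas3 (-5.49), Rtp4 (-6.27) and Oasl2 (-4.62) were among them. Of 14 tested class II antigen presentation genes, 6 were higher, 0 lower and 8 did not pass, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000774, 0.124 with an estimated correlation). Examples were H2-Eb1 (6.22), H2-Ab1 (6.70), Cd74 (6.19) and H2-Aa (7.01). Cell cycle genes had 8 higher, 0 lower and 22 not passing among 30 tested, and 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0206, 0.419 with an estimated correlation). Mcm3 (4.74), Rrm1 (4.35), Top2a (4.005, -1.57 with BM as the reference) and Stmn1 (3.62) were among them.

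Markers of several other cell types were higher in the same libraries. Among 12 tested fibroblast markers, 12 higher and 0 lower passed, 0 did not, with 12 higher and 0 lower adjusted over the list alone (camera adjusted p = 7.50e-14, 0.0844 with an estimated correlation). Examples were Col1a1 (7.59), Sparc (8.02), Col3a1 (8.38) and Pdgfra (7.18). Of 5 tested plasma cell markers, 5 were higher, 0 lower and 0 did not pass, with 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000123, 0.0844 with an estimated correlation). Derl3 (3.91), Sdc1 (6.15), Jchain (7.80) and Igha (8.48) were among them. Intestinal epithelial markers had 12 higher, 1 lower and 2 not passing among 15 tested, and 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.01e-06, 0.0844 with an estimated correlation). Examples were Muc2 (5.91), Zg16 (4.71), Lgals4 (5.73) and Krt18 (3.48). Among 14 tested endothelial markers, 11 higher and 0 lower passed, 3 did not, with 14 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.67e-08, 0.0844 with an estimated correlation). Eng (6.22), Emcn (4.82), Kdr (4.59) and Cdh5 (6.32) were among them. Of 17 tested monocyte and macrophage markers, 8 were higher, 0 lower and 9 did not pass, with 10 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.60e-05, 0.117 with an estimated correlation). Examples were Mrc1 (7.76), Apoe (4.33), C1qb (6.49) and C1qc (5.72). In all, 4196 of the 16157 genes passed, 2558 higher and 1638 lower (3029 and 1170 with median-of-ratios scaling, 2435 and 2619 with quantile normalization). In 50.1% of the tested genes the 3 libraries of one tissue all lay above the 3 of the other, against 10% by chance. The count was 6355 without the Skin libraries, 7482 with a weight per library and 6439 with only the 6 libraries compared.

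Skin against Blood showed keratinocyte and inflammatory genes higher, in libraries that varied the most. Some class II genes (5 of 14) were higher and neutrophil identity genes (16 of 24) lower, both list calls lost with an estimated correlation. Dsg1a, a desmosomal cadherin of the epidermis, was 0 in Blood and at least 1882-fold, and 823-fold without Skin replicate 2, higher in Skin, and Anxa8, a membrane-binding annexin, was at least 826-fold, and 549-fold without Skin replicate 2, higher. Dab2, an endocytic adaptor, stood at 418 ± 233 scaled counts in Skin and 0.558 ± 0.299 in Blood (log2 difference 7.93 ± 0.77 SE, limma adjusted p = 2.15e-06), and H2-Aa at 726 ± 395 and 6.17 ± 8.78 (7.31 ± 0.79). Xkrx (7.79), the mitochondrial mt-Atp6 (8.05, lost in 12 of 20 alternatives) and mt-Nd4l (0 in Blood, at least 1813-fold, and 1055-fold without Skin replicate 2, higher) and Olfr1191-ps1 (likewise at least 824-fold, and 358-fold without Skin replicate 2) were higher too. Lower in Skin were Ltf (-6.31 ± 1.06), Camp (-5.35), Ly6g (-5.12 ± 0.95, adjusted p = 0.00116 by limma), Cxcr2 (-3.03) and S100a9 (-2.41). S100a8 (-2.51) was lower by a call lost in 9 of 20 alternatives. The interferon-induced Ifi47 (-6.40) and Rtp4 (-5.78), Kirrel3 (-6.20), Tmem268 (-6.38) and the lysophospholipid acyltransferase Lpcat2 (-5.91) were lower, and the co-chaperone Dnajb1 (at least 89.8-fold lower) and Gm45837 (at least 117-fold, and 77.5-fold without Blood replicate 2, lower) were 0 in Skin. On mm10, Dsg1a (ENSMUSG00000069441) lies on chromosome 18, 20310811 to 20343350 and Ltf (ENSMUSG00000032496) on chromosome 9, 111019271 to 111042767.

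NF-kappaB response and cytokine genes had 15 higher, 1 lower and 17 not passing among 33 tested, and 16 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.12e-09, 0.00341 with an estimated correlation). Tnfaip3 (4.35), Icam1 (4.24), Nfkbia (2.53) and Ccrl2 (4.92) were among them. Among 35 tested immediate early and heat shock genes, 15 higher and 2 lower passed, 18 did not, with 17 higher and 3 lower adjusted over the list alone (camera adjusted p = 2.65e-09, 0.0281 with an estimated correlation). Examples were Nr4a1 (4.26), Hspa1b (6.08), Hspa1a (6.40) and Fosb (3.45). Of 22 tested specific and gelatinase granule genes, 0 were higher, 13 lower and 9 did not pass, with 0 higher and 16 lower adjusted over the list alone (camera adjusted p = 4.24e-07, 0.152 with an estimated correlation). Ltf (-6.31), Camp (-5.35), Ngp (-5.39) and Cyba (-3.61) were among them. Neutrophil identity genes had 1 higher, 16 lower and 7 not passing among 24 tested, and 1 higher and 17 lower adjusted over the list alone (camera adjusted p = 4.40e-05, 0.360 with an estimated correlation). Examples were Wfdc21 (-5.40), Ly6g (-5.12), Fpr1 (-5.08) and Itgb2 (-2.11). The drop was deepest in Skin replicate 1, where keratinocyte and fibroblast markers were highest: the list's mean log2 level was 5.09, 7.79 and 7.88 in replicates 1, 2 and 3, against 8.80 to 8.87 in Blood, that of keratinocyte markers 8.70, 6.25 and 4.89, and that of fibroblast markers 7.35, 4.09 and 4.70. S100a9 in the 3 replicates was 608, 8093 and 3879.7. Among 14 tested class II antigen presentation genes, 5 higher and 0 lower passed, 9 did not, with 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000128, 0.130 with an estimated correlation). Cd74 (6.22), H2-Aa (7.31), H2-Ab1 (6.42) and H2-Eb1 (5.67) were among them. Of 27 tested interferon-gamma response genes, 0 were higher, 8 lower and 19 did not pass, with 0 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.00449, 0.113 with an estimated correlation). Examples were Irgm2 (-4.87), Gbp2 (-2.95, 0.94 with BM as the reference), Ifi47 (-6.40) and Gbp7 (-2.92).

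Keratinocyte markers had 11 higher, 0 lower and 3 not passing among 14 tested, and 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.30e-18, 0.0281 with an estimated correlation). Krt1 (8.56), Krt10 (at least 3033-fold, and 1214-fold without Skin replicate 1, higher), Krt15 (at least 2380.0-fold higher) and Krt5 (9.14) were among them. Among 17 tested monocyte and macrophage markers, 10 higher and 1 lower passed, 6 did not, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.35e-07, 0.105 with an estimated correlation). Examples were Mrc1 (8.77), Apoe (3.99), Cd163 (5.59) and F13a1 (4.17). Of 12 tested fibroblast markers, 6 were higher, 0 lower and 6 did not pass, with 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.98e-08, 0.133 with an estimated correlation). Col1a1 (7.28), Col1a2 (5.39), Sparc (5.67) and Col3a1 (5.004) were among them. In all, 2597 of the 16157 genes passed, 911 higher and 1686 lower (1155 and 1126 with median-of-ratios scaling, 86 and 23 with only the 6 libraries compared). In 34.2% of the tested genes the 3 libraries of one tissue all lay above the 3 of the other. Chance is not 10%, Skin floors being higher. In simulated data with 200 genes changed, 252 unchanged genes were called among 15960 tested, 81.0% of all calls. With a weight per library it was 1 of 8 calls. Single Skin calls thus rest on an understated error, while the share itself holds for the simulated setting only. The observed count was 1147 with a weight per library and 109 with only the 6 libraries compared. It was 1389, 1394 and 1556 without Blood replicate 1, 2 and 3.

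**Figure D3:**
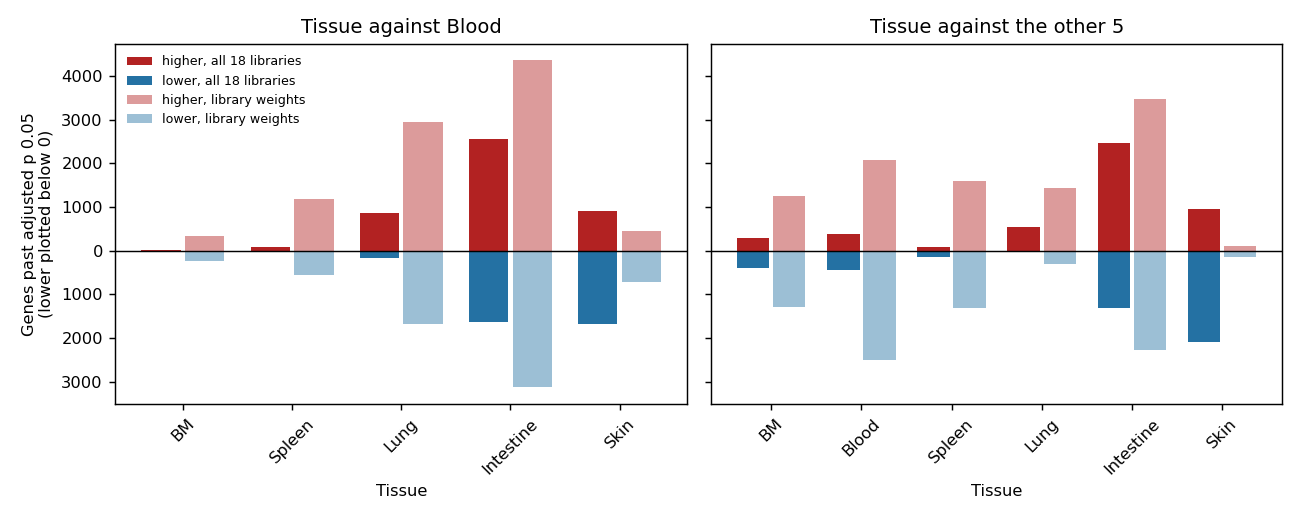
Number of genes past adjusted p 0.05, higher (up) and lower (down), for each tissue against Blood (left) and against the other 5 tissues (right), with all 18 libraries weighted alike (dark) and with a weight per library (pale). Against Blood, Intestine has 4196 genes and BM 33 with equal weights, and 7482 and 578 with a weight per library.

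Each tissue was then set against the mean of the other 5. BM stood out by its granule genes. Camp was 2806 ± 292 scaled counts in the 3 BM libraries and 35.4 ± 65.5 (SD, n = 15) in the others (log2 difference 8.12 ± 0.74 SE, limma adjusted p = 2.51e-06), followed by Ltf (7.75 ± 0.82), Ngp (7.65 ± 0.79), the integrin Itgb2l (5.997), the chitinase-like Chil3 (5.86), the transporter Abca13 (5.26), Adpgk (5.42) and 4930438A08Rik (5.26). Mpo (4.34), Ly6g (4.96), S100a8 (2.75) and S100a9 (2.69) were higher, and Il1b was lower (-1.76, lost in 17 of 33 alternatives). Fosb (-6.11 ± 0.43), Plk2 (-4.78), complement C4b (-4.62) and Csrnp1 (-4.55) were the leading lower genes. Specific and gelatinase granule genes had 14 higher, 0 lower and 8 not passing among 22 tested, and 20 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.88e-26, 0.0107 with an estimated correlation). Examples were Camp (8.12), Ngp (7.65), Ltf (7.75) and Itgb2l (5.997). Among 35 tested immediate early and heat shock genes, 0 higher and 11 lower passed, 24 did not, with 0 higher and 14 lower adjusted over the list alone (camera adjusted p = 3.19e-11, 0.0107 with an estimated correlation). Fosb (-6.11), Atf3 (-3.96), Maff (-3.95) and Egr1 (-3.76) were among them. Of 33 tested NF-kappaB response and cytokine genes, 0 were higher, 6 lower and 27 did not pass, with 0 higher and 15 lower adjusted over the list alone (camera adjusted p = 7.21e-08, 0.0107 with an estimated correlation). Examples were Tnfaip3 (-3.15), Nfkbia (-1.98), Cxcl2 (-4.08) and Nfkbiz (-1.81). Neutrophil identity genes had 10 higher, 1 lower and 13 not passing among 24 tested, and 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.45e-11, 0.180 with an estimated correlation). Cebpe (5.09), Ly6g (4.96), S100a9 (2.69) and Itgam (1.99) were among them. In all, 684 of the 16157 genes passed, 296 higher and 388 lower (187 and 460 with median-of-ratios scaling, 435 and 386 with a pseudocount of 5, 700 and 651 without Skin replicate 3, 1083 and 455 with voom weights, 372 and 273 without Skin and Intestine). The count was 2232 without the Skin libraries and 2548 with a weight per library. It was 364, 153 and 232 without BM replicate 1, 2 and 3. It was 1232, 1984 and 1351 without Skin replicate 1, 2 and 3, and 1109 without the Blood libraries.

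Some interferon-induced genes stood higher and some class II genes lower in Blood, while the lists of type I interferon and class II genes were lost with an estimated correlation. Of the 26 lists called, 2 held with an estimated correlation. Apol11b was 64.3 ± 23.7 scaled counts in Blood and 0.940 ± 3.06 (n = 15) elsewhere (log2 difference 5.53 ± 0.61 SE, limma adjusted p = 1.28e-05). Rtp4, an interferon-induced chaperone of receptors (4.11 ± 0.84), Steap4, a metalloreductase (3.78), Adam30 (4.12), Kirrel3 (4.06), Dnajb13 (3.93) and the transglutaminase Tgm1 (3.57) were among the leading higher genes. Eif2s3y (-5.78), H2-Aa (-5.76 ± 0.62), H2-Ab1 (-5.26) and Cd74 (-4.78) were lower. Cxcr2 (2.55), Ly6g (2.94), S100a8 (2.33) and S100a9 (2.14) were higher in Blood, as was Camp (2.53, lost in 22 of 32 alternatives). Among 30 tested type I interferon response genes, 5 higher and 0 lower passed, 25 did not, with 16 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.13e-09, 0.137 with an estimated correlation). Examples were Oas3 (3.08), Rtp4 (4.11) and Oasl2 (2.81). Of 27 tested interferon-gamma response genes, 7 were higher, 1 lower and 19 did not pass, with 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.76e-06, 0.0392 with an estimated correlation). Gbp2 (3.15), Irgm1 (2.41), Gbp7 (2.30) and H2-D1 (1.43) were among them. Neutrophil identity genes had 9 higher, 0 lower and 15 not passing among 24 tested, and 19 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.21e-10, 0.133 with an estimated correlation). Examples were S100a9 (2.14), Wfdc21 (2.75) and Cxcr2 (2.55). Among 14 tested class II antigen presentation genes, 0 higher and 6 lower passed, 8 did not, with 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 3.86e-07, 0.0906 with an estimated correlation). H2-Ab1 (-5.26), Cd74 (-4.78), H2-Aa (-5.76) and H2-Eb1 (-4.47) were among them. Mean log2 levels of B-cell markers were 1.97 to 2.66 in Blood, 1.75 to 2.69 in Skin and 3.26 to 7.54 elsewhere. Of 10 tested erythroid markers, 7 were higher, 0 lower and 3 did not pass, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.13e-09, 0.0312 with an estimated correlation). Examples were Hbb-bt (6.55), Hbb-bs (5.31), Alas2 (5.01) and Hba-a2 (4.64). In all, 842 of the 16157 genes passed, 392 higher and 450 lower (234 and 509 with median-of-ratios scaling, 502 and 439 with a pseudocount of 5, 812 and 735 without Skin replicate 3, 1198 and 511 with voom weights). The count was 2699 without the Skin libraries and 4574 with a weight per library. It was 144, 130 and 300 without Blood replicate 1, 2 and 3. It was 1340, 2160 and 1547 without Skin replicate 1, 2 and 3.

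Spleen stood out by B-cell genes, and 11 of 14 markers higher together argue against neutrophils as the only source. Ikzf3 (3.85 ± 0.65 SE, limma adjusted p = 0.00283), at 159 ± 47.5 scaled counts against 19.4 ± 18.9 (n = 15), led with Fcmr, the receptor for IgM (3.83), the class II chains H2-Ob (3.69) and H2-DMb2 (2.81), the transcription factors Spib (3.36, lost in 8 of 33 alternatives) and Bcl11a (2.87), and Ralgps2 (2.48, lost in 16 of 33). Among the genes lower in Spleen were Dpt at -4.75, Postn at -4.44 (lost in 8 of 33), Myh11 at -4.28 and Lama4 at -4.23. B-cell markers had 11 higher, 0 lower and 3 not passing among 14 tested, and 14 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.47e-24, 0.00367 with an estimated correlation). Pax5 (5.14), Blk (4.60) and Ighm (3.96) were among them. Among 14 tested class II antigen presentation genes, 2 higher and 0 lower passed, 12 did not, with 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000459, 0.149 with an estimated correlation). H2-DMb2 (2.81) and H2-Ob (3.69) passed, while Ciita (2.52) and H2-Ab1 (1.22) did not. Of 28 tested angiogenic factors, 0 were higher, 3 lower and 25 did not pass, with 0 higher and 9 lower adjusted over the list alone (camera adjusted p = 2.40e-05, 0.00367 with an estimated correlation). Thbs1 (-4.14), Nrp1 (-3.77) and Anxa3 (-2.51, lost in 14 of 33 alternatives) passed, while Pdgfb (-2.19) did not. Fibroblast markers had 0 higher, 9 lower and 3 not passing among 12 tested, and 0 higher and 12 lower adjusted over the list alone (camera adjusted p = 2.80e-25, 0.0148 with an estimated correlation). Examples were Col3a1 (-5.44), Sparc (-4.88), Col1a1 (-4.27) and Col1a2 (-3.79). In all, 232 of the 16157 genes passed, 87 higher and 145 lower (59 and 168 with median-of-ratios scaling, 1596 and 1308 with a weight per library, 712 and 272 with voom weights, 128 and 96 without Skin and Intestine). The count was 814 without the Skin libraries and 2904 with a weight per library. It was 45, 51 and 39 without Spleen replicate 1, 2 and 3. It was 412, 668 and 490 without Skin replicate 1, 2 and 3, and 396 without the Blood libraries.

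Lung stood out by vascular and epithelial genes and by inflammatory regulators. Adgrf5 was 1096 ± 584 scaled counts in Lung and 68.4 ± 115 (n = 15) elsewhere (log2 difference 6.15 ± 0.62 SE, limma adjusted p = 6.01e-06). Cyp4b1 (6.26 ± 0.65), Sec14l3 (6.11), the chloride channel protein Clic5 (5.58), the methyltransferase Inmt (5.43), the matrix protein Npnt (5.37), the water channel Aqp1 (5.14) and the noradrenaline transporter Slc6a2 (5.08) were higher, and no gene met the rule for the leading lower genes. Il1b was higher in Lung (2.24 ± 0.49, adjusted p = 0.00931 by limma) and Camp lower (-4.62 ± 0.74). Among 33 tested NF-kappaB response and cytokine genes, 13 higher and 0 lower passed, 20 did not, with 16 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.04e-16, 0.000289 with an estimated correlation). Tnfaip3 (4.11), Nfkbiz (2.94), Nfkbia (2.75) and Il1a (4.20) were among them. Of 35 tested immediate early and heat shock genes, 10 were higher, 0 lower and 25 did not pass, with 21 higher and 0 lower adjusted over the list alone (camera adjusted p = 7.73e-18, 0.00180 with an estimated correlation). Examples were Fosb (3.72), Nr4a1 (3.70), Nr4a3 (4.48) and Atf3 (2.87). Angiogenic factors had 5 higher, 0 lower and 23 not passing among 28 tested, and 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00763, 0.0282 with an estimated correlation). Thbs1 (2.04), Apln (3.51), Nrp1 (3.53) and Pdgfb (2.76) were among them. Among 14 tested endothelial markers, 13 higher and 0 lower passed, 1 did not, with 14 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.02e-27, 0.00302 with an estimated correlation). Examples were Cdh5 (6.15), Kdr (4.29), Tek (5.40) and Calcrl (3.07). Of 11 tested lung epithelial markers, 8 were higher, 0 lower and 3 did not pass, with 9 higher and 0 lower adjusted over the list alone (camera adjusted p = 6.48e-15, 0.0282 with an estimated correlation). Cldn18 (5.89), Slc34a2 (6.52), Lamp3 (4.62) and Sftpc (7.20) were among them. In all, 553 of the 16157 genes passed, 533 higher and 20 lower. The count was 1215 (1018 and 197) without the Skin libraries and 1720 (1424 and 296) with a weight per library. It was 205 and 240 without Lung replicate 1 and 2, and 297 without the Blood libraries. It was 2739 (1676 and 1063) without the Skin and Intestine libraries, where Ly6g lay at -1.76 in place of 0.26.

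The leading genes of Intestine against the others included several of the extracellular matrix. Of the 16 lists called, 0 held with an estimated correlation. Adamdec1 was 1764 ± 841 scaled counts in Intestine and 3.08 ± 3.58 (n = 15) elsewhere (log2 difference 9.14 ± 0.62 SE, limma adjusted p = 9.38e-09). Tnc (7.78 ± 1.04), Postn (7.30), Myh11 (7.24), the laminin Lamb1 (7.04), Col12a1 (6.98), Col6a3 (6.86) and Hhip, an antagonist of hedgehog signalling (6.69), were higher. Padi4, the enzyme that citrullinates histones (-5.26 ± 0.49), Stfa2l1 (-5.10), Vnn3 (-5.07) and Rufy4 (-4.54) were lower, with S100a9 (-4.25), Cxcr2 (-4.12), Ly6g (-4.17) and Cxcr4 (-2.44). Neutrophil identity genes had 0 higher, 22 lower and 2 not passing among 24 tested, and 0 higher and 22 lower adjusted over the list alone (camera adjusted p = 9.97e-20, 0.0713 with an estimated correlation). Examples were S100a9 (-4.25), Itgb2 (-2.84) and Mxd1 (-3.50). Among 9 tested genes of factors that help B cells, 3 higher and 0 lower passed, 6 did not, with 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0735, 0.408 with an estimated correlation, not called). Cxcl12 (6.04), Cxcl13 (3.07) and Tnfsf13 (1.84, lost in 18 of 32 alternatives) passed, while Tnfsf13b (1.17) did not. Of 12 tested fibroblast markers, 12 were higher, 0 lower and 0 did not pass, with 12 higher and 0 lower adjusted over the list alone (camera adjusted p = 4.89e-15, 0.0713 with an estimated correlation). Examples were Col3a1 (7.14), Fbln1 (6.82), Sparc (5.98) and Col1a1 (5.49). Plasma cell markers had 5 higher, 0 lower and 0 not passing among 5 tested, and 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 6.44e-05, 0.0713 with an estimated correlation). Derl3 (3.66), Igha (8.55), Jchain (6.47) and Sdc1 (3.81) were among them. In all, 3782 of the 16157 genes passed, 2460 higher and 1322 lower (3076 and 989 with median-of-ratios scaling, 2408 and 2187 with quantile normalization). The count was 6162 without the Skin libraries and 5749 with a weight per library. It was 2479 without Intestine replicate 2.

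Skin stood out by genes of stratified epithelium. Dsg1a was 626 ± 644 scaled counts in Skin and 0.512 (at most 5.91, n = 15) elsewhere (log2 difference 8.12 ± 0.70 SE, limma adjusted p = 3.61e-07). Col17a1, the collagen of hemidesmosomes (6.99 ± 0.78), Anxa8 (6.70), the epidermal transcription factor Trp63 (6.65), Pou1f1 (6.64), the protease inhibitor Spink5 (6.36), the desmocollin Dsc3 (6.19) and Trim29 (5.79) were higher. Tmbim4 (-4.90), Manba (-4.76) and Tor4a (-4.75) were lower, and Ptger1, 0 in Skin, was at least 44.1-fold lower. Il1b was higher in Skin by a call lost in 18 of 31 alternatives (1.46 ± 0.49), and Ltf (-4.93), Camp (-3.89) and Ly6g (-3.21) were lower. Among 14 tested keratinocyte markers, 11 higher and 0 lower passed, 3 did not, with 12 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.33e-22, 0.0125 with an estimated correlation). Examples were Krt1 (8.57), Krt10 (8.87), Krt5 (8.50) and Krt15 (7.83). Of 33 tested NF-kappaB response and cytokine genes, 13 were higher, 0 lower and 20 did not pass, with 21 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.72e-12, 0.00102 with an estimated correlation). Tnfaip3 (3.13), Nfkbia (2.14), Icam1 (3.03) and Cxcl2 (4.19) were among them. Immediate early and heat shock genes had 15 higher, 1 lower and 19 not passing among 35 tested, and 18 higher and 2 lower adjusted over the list alone (camera adjusted p = 9.07e-12, 0.0115 with an estimated correlation). Examples were Fosb (3.04), Maff (3.70), Dnajb1 (at least 67.8-fold lower) and Atf3 (2.82). Among 26 tested unfolded protein and oxidative stress genes, 10 higher and 2 lower passed, 14 did not, with 10 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0112, 0.0418 with an estimated correlation). Atf4 (1.94), Slc7a11 (1.90), Txnrd1 (1.81) and Herpud1 (-2.37) were among them. In all, 3037 of the 16157 genes passed, 953 higher and 2084 lower (1247 and 1575 with median-of-ratios scaling, 1358 and 1548 with quantile normalization). The count was 245 with a weight per library. In simulated data 93.5% of the calls were of unchanged genes, a share that holds only for the 200 genes changed there.

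**Figure D4:**
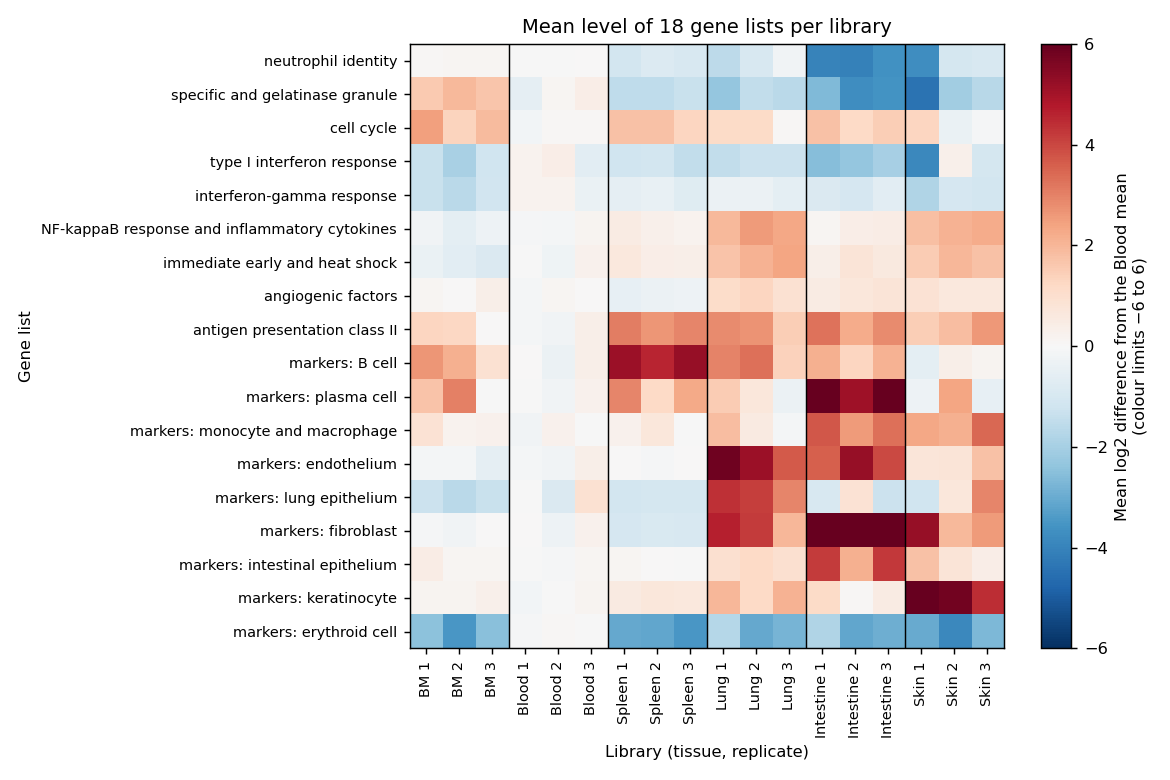
Mean log2 difference from the Blood mean (colour, limits -6 to 6) of 18 of the fixed gene lists (listed at the left) in each of the 18 libraries (along the bottom). Fibroblast markers are higher in the 3 Intestine libraries and keratinocyte markers in the 3 Skin libraries than in Blood.

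**Figure D5:**
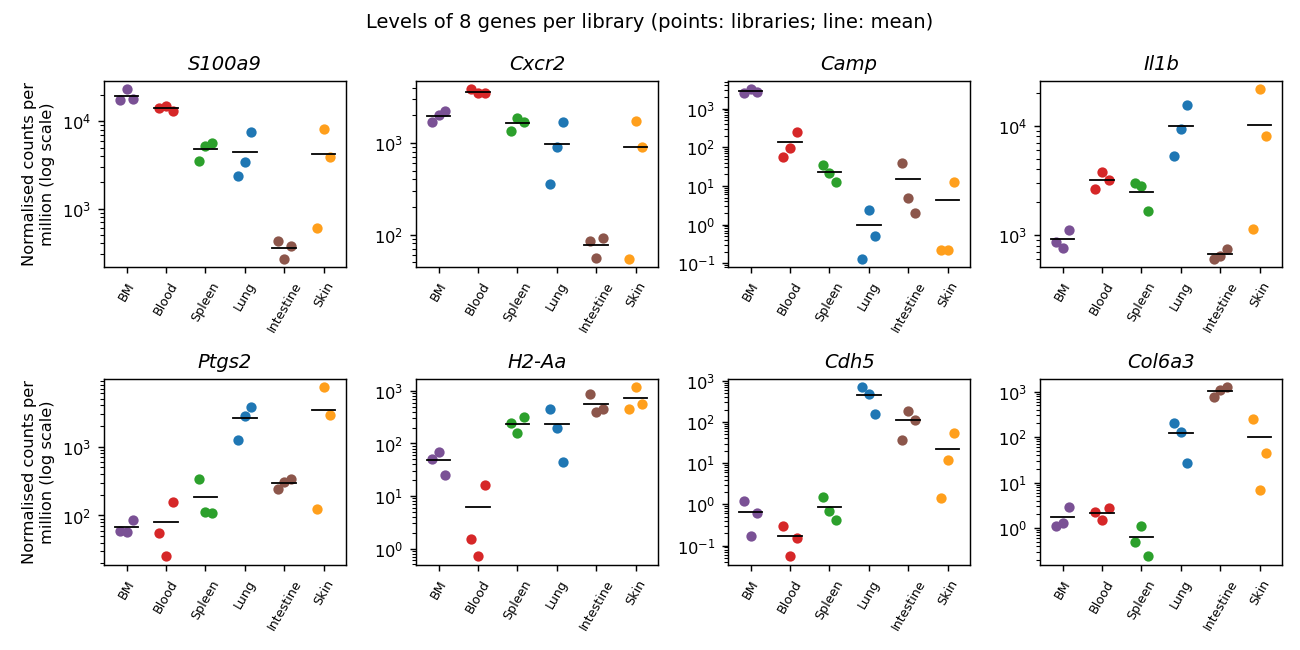
Scaled counts (log axis) of S100a9, Cxcr2, Camp, Il1b, Ptgs2, H2-Aa, Cdh5 and Col6a3 in each of the 18 libraries (points) with the mean of each tissue (line). Cdh5 is 698, 467 and 153 in the Lung libraries and 0.299, 0.0544 and 0.156 in Blood, and Il1b is 5329, 9252 and 15314 and 2640.3, 3745 and 3195.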

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

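Of the alternatives fixed before the data were examined, these moved a count of genes by over 1.5 times, and the cause was not tested. With a pseudocount of 5, genes passing were 71 in BM against Blood. With quantile normalization, genes passing were 73 in BM against Blood, 1317 in Blood against the others and 676 in Spleen against the others. With a replicate block by letter, genes passing were 58 in Spleen against Blood, 1730 in Skin against Blood, 445 in Blood against the others and 122 in Spleen against the others. With a weight per library, genes passing were 8306 in the F test, 578 in BM against Blood, 1725 in Spleen against Blood, 4626 in Lung against Blood, 7482 in Intestine against Blood, 1147 in Skin against Blood, 2548 in BM against the others, 4574 in Blood against the others, 2904 in Spleen against the others, 1720 in Lung against the others, 5749 in Intestine against the others and 245 in Skin against the others. Without Skin replicate 1 and Blood replicate 2, genes passing were 20 in BM against Blood, 37 in Spleen against Blood and 275 in Blood against the others. With only the 6 libraries compared, genes passing against Blood were 463 in BM and 1155 in Spleen. They were 2377 in Lung, 6439 in Intestine and 109 in Skin. The following alternatives were chosen after seeing the data. With voom weights on the estimated counts, they were 87 in BM against Blood, 213 in Spleen against Blood, 1538 in BM against the others, 1709 in Blood against the others, 984 in Spleen against the others, 974 in Lung against the others and 1989 in Skin against the others. Without the Skin libraries, they were 339 in BM against Blood, 400 in Spleen against Blood, 2533 in Lung against Blood, 6355 in Intestine against Blood, 2232 in BM against the others, 2699 in Blood against the others, 814 in Spleen against the others, 1215 in Lung against the others and 6162 in Intestine against the others. Without the Skin and Intestine libraries, they were 2948 in the F test, 358 in BM against Blood, 386 in Spleen against Blood, 2683 in Lung against Blood and 2739 in Lung against the others. Without the Blood libraries, they were 1109 in BM against the others, 396 in Spleen against the others and 297 in Lung against the others. With BM as the reference, they were 48 in Spleen against Blood. Leaving out 1 of the 18 libraries in turn gave 4254 to 6502 in the F test, 153 to 1984 in BM against the others, 130 to 2160 in Blood against the others, 39 to 668 in Spleen against the others, 205 to 759 in Lung against the others, 2479 to 4958 in Intestine against the others and 2417 to 3803 in Skin against the others. Leaving out 1 of the 6 libraries compared gave 11 to 27 in BM against Blood, 23 to 65 in Spleen against Blood, 463 to 1341 in Lung against Blood, 3018 to 3506 in Intestine against Blood and 1389 to 3530 in Skin against Blood. The list tests called 192 times and 40 times with an estimated correlation, 152 lost. Calls lost were 4 with median-of-ratios scaling, 9 with quantile normalization, 45 with the self-contained test fry and 13 of 165 without the Skin libraries. The trafficking and adhesion list in Spleen against Blood changed direction with quantile normalization (adjusted p = 0.994, 0.0280 as reported, cause not tested). Genes changed direction, the cause not tested, as follows: Ly6g in Lung against the others without the Skin and Intestine libraries (-1.76 in place of 0.26), and with BM as the reference in place of Blood in Intestine Top2a (-1.57 in place of 4.005), in Lung Alas2 (0.97 in place of -4.30), Hbb-bs (1.83 in place of -4.11), Ear2 (-0.28 in place of 4.06) and Hbb-bt (1.08 in place of -5.75), in Skin Gbp2 (0.94 in place of -2.95) and in Spleen Mpo (-3.97 in place of 0.06), Gbp2 (0.76 in place of -3.13) and Apol11b (0.17 in place of -5.62). Replicates share a number, and their descriptions a letter, A to C in the order of the numbers but D for Blood replicate 3. Those of Skin replicate 1 and Blood replicate 2 end in rep. The labels state neither what the letters mark nor what rep means. Samples with the same number did not deviate together: 45 pairs correlated at -0.0604 to 0.106, 1 over 0.1, and 7 of 18 libraries correlated best with their own number. By letter, 40 pairs correlated at -0.0488 to 0.106, 1 over 0.1, and 7 libraries correlated best with their own letter. Pairing was therefore not used. With the replicate block the counts were 5084 in the F test, 31 in BM against Blood, 80 in Spleen against Blood, 956 in Lung against Blood, 4190 in Intestine against Blood, 2542 in Skin against Blood, 684 in BM against the others, 816 in Blood against the others, 195 in Spleen against the others, 517 in Lung against the others, 3787 in Intestine against the others and 2972 in Skin against the others, within 1.5 times of those reported, and 193 list tests were called, with no reported list call lost. Lung replicate 1 held the fewest estimated counts, 2.94e+06, which limits what it can show of the lowest genes.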

Other observations

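The gene list tests, the test of shared reads and the other splits of the libraries were set before their results were seen, and the other tests in this part were chosen after. The next 2 gene lists are from Intestine against Blood. Of 32 tested ribosomal protein genes, 8 were higher, 1 lower and 23 did not pass, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00249, 0.247 with an estimated correlation). Examples were Rpl4 (2.29), Rps4x (2.34) and Rps2 (2.44). Glycolysis and hypoxia genes had 0 higher, 7 lower and 24 not passing among 31 tested, and 0 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.00510, 0.0988 with an estimated correlation, 0.0751 with quantile normalization). Slc2a3 (-3.73), Pkm (-2.26), Gpi1 (-2.07) and Bnip3l (-1.99) were among them. Another 2 lists are from Lung against Blood. Among 17 tested circadian clock genes, 2 higher and 0 lower passed, 15 did not, with 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0162, 0.173 with an estimated correlation). Bhlhe40 (2.24, lost in 8 of 22 alternatives) and Nr1d2 (at least 94.9-fold higher, lost in 9 of 22 alternatives) passed, while Bhlhe41 (2.69) and Rora (3.001) did not. Of 24 tested trafficking and adhesion genes, 6 were higher, 0 lower and 18 did not pass, with 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.652, 0.839 with an estimated correlation, not called, with a median log2 difference of -0.71, a mean of 0.24 and the test pointing lower). Ccrl2 (5.68), Pecam1 (3.48), S1pr1 (4.97) and Icam1 (3.14) were among them.

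Il1b was also set against S100a9 in each library. The ratio averaged 0.0480 ± 0.0148 in BM (SD, n = 3), 0.225 ± 0.0360 in Blood, 0.565 ± 0.287 in Spleen, 2.33 ± 0.338 in Lung, 1.94 ± 0.494 in Intestine and 2.20 ± 0.405 in Skin. Each tissue's 3 ratios lay all on one side of the 3 in Blood (exact permutation p = 0.1 each, the smallest that 3 against 3 can give).

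The Y-linked Ddx3y and Eif2s3y averaged 4.91 ± 5.65 and 0.348 ± 0.312 in Blood (SD, n = 3) and 137 ± 109.6 and 87.9 ± 57.8 in the other 15 libraries. Depth was excluded (214 counts expected in the shallowest Blood library). Uty and Kdm5d, Y-linked too, averaged 28.9 ± 11.01 and 30.2 ± 7.63 in Blood, and 27.2 to 728 and 1.87 to 90.4 elsewhere. These values argue against a female origin of the Blood libraries unless reads of other genes lie behind them. Uty and Kdm5d share 3.59% and 6.86% of their windows with other genes, against 1.54% and 0.448% for Ddx3y and Eif2s3y. What such a share brings was not tested, so shared reads and a female origin stay open. The X-linked partners Kdm5c (1.41), Kdm6a (1.21), Eif2s3x (0.34) and Ddx3x (-0.39) did not pass. Their median log2 difference of 0.78 is raised by Skin replicate 2, low for the first 3 (3.68, 1.52 and 2.38). Xist was not among the tested genes. With a female origin, sex would be mixed into every comparison with Blood.

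Neutrophil genes were low and stromal, epithelial and plasma cell genes high in the 3 Intestine libraries. That 91.7% of the neutrophil identity genes were lower than in Blood restates this and decides nothing, since less neutrophil RNA and changed neutrophils would both give it. A lower depth was excluded (lowest effective library 9.40 times 1e6 counts). The sort (typically over 95% pure) should remove other cells, and what RNA came through was not measured. Fibroblast and plasma cell marker means (Intestine at least 8.80 and 6.98 log2, Blood at most 2.42 and 2.14) argue against changed neutrophils alone. Whether they changed too is open.

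In Lung, endothelial markers were 1.92 log2 units higher (median) in replicate 1 than in replicate 3, while the NF-kappaB members higher in Lung had a median of -0.48 and the angiogenic members 1.22. NF-kappaB members also stayed under endothelial markers in replicate 2 minus 3 (0.22 against 1.45) and 1 minus 2 (-0.65 against 0.59). The neutrophil identity list had medians of -1.49 (1 minus 3), -0.81 (2 minus 3) and -0.68 (1 minus 2). NF-kappaB members did not follow it in 2 minus 3 either. These medians argue against endothelial RNA of fixed make-up as the only source of NF-kappaB genes (9 lower, 5 higher in replicate 1 than 3). Single and angiogenic ones stay open. Dilution of Blood-like neutrophils was excluded for Il1b, whose lowest ratio to S100a9 in Lung was 2.05 against a highest of 0.250 in Blood. Other cell types were not tested.

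Other splits of the same libraries were drawn. Of 100 splits, the real one included, 1 reached the real count in the F test (highest other 617), 4 reached the real count in BM against the others (highest other 1461), 2 reached the real count in Blood against the others (highest other 1454), 2 reached the real count in Spleen against the others (highest other 625), 1 reached the real count in Lung against the others (highest other 36), 1 reached the real count in Intestine against the others (highest other 48) and 1 reached the real count in Skin against the others (highest other 2380). The 5 other splits that reached the real count, in BM, Blood and Spleen, each put at least 2 libraries of Skin and Intestine into the group of 3, and 2 of them put all 3 Skin libraries there, a structure of the samples. For the comparisons with Blood 10 splits of 6 libraries are too few, and the real counts stood beside highest others of 1 in BM (33 real), 1 in Spleen (98 real), 0 in Lung (1017 real), 0 in Intestine (4196 real) and 1 in Skin (2597 real).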
